A study of Homo sapiens with 18 samples.

How the data were processed

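RNA from DU145 cells was compared between GC7 and vehicle in whole-cell, cytoplasmic and heavy polysomal RNA, with 3 libraries in each of 6 groups, per the labels. Per the labels' protocols, cells received emetine before hypotonic lysis, nuclei and then mitochondria were removed by centrifugation, and polysomes were separated on sucrose gradients. Per the submitters' processing notes, STAR 2.7.8a, Salmon 1.4.0 and the build GRCh38 were used, in a role and order not given in the sources used here. Groups were taken from the labels, and no column of per-library values was used.

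The values are the authors' comparison tables. Per the file headers, the whole-cell table gives a log fold change and an unadjusted p-value for 44682 genes. Its base was read from the deposited values as log2: the step from no reads to 1 read in 1 library was 0.5283, and log2(1.5/0.5)/3 is 0.5283. Genes without reads share a deposited log2 value of 0.0711 (18021 genes within 0.00015). The table holds 5099 rows named as numbered copies of a symbol, which were left out of the list background. Per the file headers, the fraction table gives for 15747 genes a mean normalized count, a log2 fold change with its SE, a p-value and an adjusted p-value in cytoplasm and polysomes, and a category. The category in the authors' deposited table matched an adjusted p under 0.05 with a log2 fold change over 1 in size for all 15747 genes. In 1373 names a comma stands in place of a point.

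Neither table states its numerator. The category "UP" was read as higher with GC7. The whole-cell values correlate negatively with those of the fractions as deposited, so their sign was reversed. This is a reading and not a statement of the authors, and all directions rest on it.

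The deposited fold changes of the fractions are shrunken, since their ratio to the SE does not give the deposited p-values. A Cauchy prior on the natural log scale was fitted by matching those p-values (scale 0.195 for cytoplasm and 0.205 for polysomes), and the unshrunken fold change and SE were computed from it. The recovered z lay within 0.1 of that of the deposited p-value for 97.4% and 99.5% of genes, and genes off by over 0.5 were left out. Values of genes and medians of lists in single comparisons are as deposited unless named as unshrunken. Shrinkage makes those of the fractions smaller in size, as for the polysomal median of the collagen list, 0.2 as deposited and 0.38 unshrunken. Sizes are therefore not compared between whole cells and fractions. Unshrunken values serve the comparison of translational efficiency, the correlations, the medians of genes grouped or matched by coding length, and the comparisons of mitochondrial RNAs with each other and with nuclear copies in the closing section. Translational efficiency was tested as polysomal minus cytoplasmic unshrunken log2 fold change, with a normal test and Benjamini-Hochberg adjustment. The planned tests on read counts could not be run on tables of comparisons, and the adjusted p-values of the fractions are the authors' own. Whole-cell p-values were adjusted by Benjamini-Hochberg over all genes.

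The 41 gene lists and the rule for named genes were fixed before the data were examined. Lists with at least 5 measured members were tested with cameraPR of limma 3.58.1 in R 4.3.3, on signed z values from the p-values, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over lists within a comparison. An estimated correlation needs per-library values and was not computed, so a preset correlation of 0.05 was used in its place. Counts of list members use the deposited adjusted p, or the unadjusted p in whole cells, where "adjusted over the list alone" adjusts the p-values of the members only. Named genes were, per comparison, the 8 highest and the 8 lowest among called genes with at least 2 log2 CPM, computed from the mean normalized count over the sum of all genes, without clone, pseudogene or antisense names, then 11 genes of the pathway, and up to 4 members of each called list and 2 of others by smallest p. The part of the rule that asked for replicates without overlap could not be checked. The text gives a selection of them. MT-RNR1, MT-RNR2, nuclear copies of mitochondrial genes and single genes of translational efficiency were chosen after their values were seen.

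Tests were tried on simulated data. With the real SE of 15669 genes, 75.0% of genes changed by 2 and 98.0% of those changed by 4 on the log2 scale were called in translational efficiency, and 11 of 15469 unchanged genes. The errors of cytoplasm and polysomes were drawn independently, which may not hold for the real data, and changes smaller than 2 were not simulated. A shifted list was called in 4 of 4 simulated comparisons, and other lists in 1 of 144 tests. These z values were drawn independently for each gene, so the 1 of 144 does not show how often lists of correlated genes are called falsely. Coordinates, coding sequences, GC content and motifs come from GENCODE 44 on GRCh38, with a coding sequence for 81.9% of genes of the fraction table. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6 were used. Alternatives were a size threshold, other thresholds and backgrounds, leaving out mitochondrial genes, deposited in place of unshrunken values, assumed error correlations, other settings of the list test, and the collagen list without members shared with the fibroblast list.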

Results

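DU145, an androgen receptor-negative line from a metastatic prostate carcinoma, was treated for 24 h with 40 µM GC7 or with vehicle. GC7 inhibits deoxyhypusine synthase (DHPS), the first enzyme of the pathway that places hypusine on the translation factor eIF5A. RNA was sequenced from whole cells, from cytoplasmic lysates and from the heavy polysome fractions of sucrose gradients, in 6 groups of 3 libraries, 18 in all. The values are the authors' comparison tables, with no per-library values, so the depth of each library is unknown and no SD between replicates can be given. The labels do not say whether the replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. Mean normalized counts summed to 29272958 over the 15747 genes of the authors' deposited table for cytoplasm and to 32579359 for polysomes, with medians of 401 and 572 per gene. Neither table states which group is the numerator. Directions below read the authors' category "UP" as higher with GC7 and reverse the sign of the whole-cell table, and on the opposite reading every direction turns round. Whole-cell values credited below to the authors' deposited table carry this reversed sign.

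The first comparison asked which transcripts of whole cells changed with GC7. Mitochondrially encoded mRNAs were lower and targets of ATF4, the transcription factor of the integrated stress response, were higher as groups, while no single gene passed adjustment. By the authors' deposited table with its sign reversed, the 13 mitochondrially encoded mRNAs had a median log2 fold change of -2.14, and all 13 were lower at an unadjusted p under 0.05 (list adjusted p = 2.12e-30). Among them, the values of the authors' deposited table were -3.47 for MT-CO3 (unadjusted p = 0.000101), -2.86 for MT-CO2 and -2.69 for MT-ND6. The mitochondrial 12S rRNA, MT-RNR1, stood at 2.29 (unadjusted p = 0.000527) and the 16S rRNA, MT-RNR2, at -1.15 (unadjusted p = 0.012) in the authors' deposited table. The 43 measured ATF4 targets had a median of 1.43, with 26 higher at an unadjusted p under 0.05 and none lower, and 23 higher when adjusted over the list alone (list adjusted p = 1.73e-42). They included CHAC1, a glutathione-degrading enzyme, at 3.16, TRIB3 at 3.28, STC2 at 2.32 and DDIT3 at 2.21 in the authors' deposited table.

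Host genes of small nucleolar RNAs with a 5′ terminal oligopyrimidine tract were also higher in whole cells, with a median of 0.82 over 13 members (list adjusted p = 2.31e-05). Immediate early genes had a median of 0.50 over 28 members (list adjusted p = 1.69e-06) and interferon-stimulated genes 0.43 over 27 (list adjusted p = 6.16e-05), a list that did not pass in cytoplasm, at a median of -0.02 (list adjusted p = 0.973), or in polysomes, at 0.02 (list adjusted p = 0.325). Autophagy and lysosome genes had a median of 0.23 over 32 members (list adjusted p = 0.0284), a call that ended at a preset correlation of 0.05 (adjusted p = 0.184), with fold changes in place of z (adjusted p = 0.158) and over all whole-cell genes with reads (adjusted p = 0.0856). Lower as groups were heat shock chaperones, at a median of -0.72 over 15 members (list adjusted p = 2.31e-05), DNA replication genes at -0.48 over 42, mitosis genes at -0.41 over 38 and cholesterol synthesis genes at -0.33 over 24. Their list adjusted p-values were 6.16e-05, 0.000213 and 0.0122 for the last 3, and the cholesterol call ended at a preset correlation of 0.05 (adjusted p = 0.101). Few single members of these lists had an unadjusted p under 0.05 in the authors' deposited table: 2 of 13 small nucleolar host genes, 4 of 28 immediate early, 3 of 27 interferon-stimulated and 1 of 32 autophagy genes were higher, and 1 of 15 chaperones, 1 of 42 DNA replication, 1 of 38 mitosis and 1 of 24 cholesterol genes were lower. Adjusted over the list alone, 1 host gene and 1 interferon-stimulated gene passed and none of the others. Members that reached this unadjusted p in the authors' deposited table include GAS5 at 1.84, FOSB at 2.08, OASL at 2.12, HSPH1 at -1.23, CLSPN at -1.19 and LSS at -0.77, with unadjusted p-values of 0.00248, 0.00214, 0.000766, 0.0251, 0.0308 and 0.0444. After Benjamini-Hochberg adjustment of the deposited p-values over 44682 genes, 0 passed 0.05 and the smallest adjusted p was 0.642. At an unadjusted p under 0.05 the authors' deposited table held 1336 genes, 741 higher and 595 lower, all among the 26661 genes with reads, of which 1333 would pass by chance with uniform p-values. Among the 14114 genes also measured in the fractions, 294 were higher and 160 lower at that threshold, fewer than uniform p-values give. The near match over all genes with reads is thus no evidence that the p-values were uniform. The table gives neither counts nor standard errors, so no other test of single genes was made.

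In cytoplasmic RNA the same question was put to the lysate from which nuclei and mitochondria had been pelleted. GDF15, a secreted stress cytokine, and the cytokine IL24 rose most among named genes, and mitochondrially encoded mRNAs fell most. In the authors' deposited table GDF15 (chromosome 19, 18374731 to 18389176, GRCh38) had a log2 fold change of 3.56 with an SE of 0.31 (adjusted p = 1.4e-28). The same table gives 3.09 for IL24 (SE 0.39), 2.57 for IL1RL1 (SE 0.31), 2.35 for CLGN (SE 0.43), 2.23 for ALDH1L2 (SE 0.45) and 1.93 for LCN2 (SE 0.25), all from the authors' deposited table. At the lower end the authors' deposited table gives -4.46 for MT-CYB (SE 0.60), -3.97 for MT-CO2 (SE 0.28), -3.95 for MT-CO3 (SE 0.54) and -3.75 for MT-ND4 (SE 0.46). Over all genes, 668 of 15747 had a deposited adjusted p under 0.05 in the authors' deposited table, 361 higher and 307 lower, and 166 of them also had a fold change over 1 in size.

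The 13 mitochondrially encoded mRNAs had a cytoplasmic median of -3.64 in the authors' deposited table, with 12 called lower, and all 13 lower when adjusted over the list alone (list adjusted p = 1.66e-75). MT-ND6, encoded on the other strand from the remaining mRNAs (chromosome M, 14149 to 14673), was the member without a call, at -0.50 (SE 0.27, adjusted p = 0.0868) in the authors' deposited table. MT-RNR1 stood at -2.42 (SE 0.40) and MT-RNR2 at -2.92 (SE 0.42) in the authors' deposited table. Nuclear copies of mitochondrial genes, which are uncertain because reads may be shared with them, had deposited values of -3.76 for MTND4P12 and -3.35 for MTND2P28 in the authors' deposited table. Mitochondrial genes took 11.9% of the summed mean normalized counts of cytoplasm and 0.685% of those of polysomes in the authors' deposited table.

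**Figure D1:**
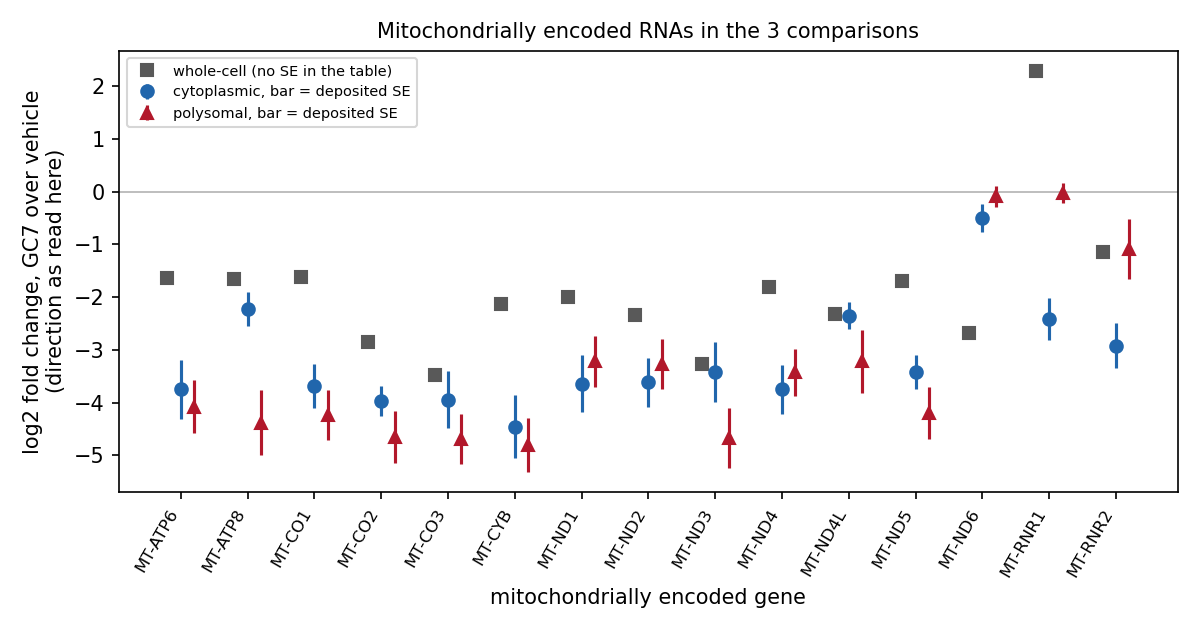
Log2 fold changes from the authors' deposited table, on the vertical axis, for each mitochondrially encoded mRNA and rRNA on the horizontal axis. Squares are whole-cell values with the sign reversed, circles are cytoplasmic and triangles polysomal values with the deposited SE. Cytoplasmic and polysomal values are shrunken, so their sizes are not compared with those of whole cells. MT-ND6 lies at -0.50 in cytoplasm and -0.09 in polysomes, and MT-RNR1 at 2.29 in whole cells and -2.42 in cytoplasm.

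ATF4 targets were higher in cytoplasm, with 24 of 43 called higher and 1 lower, 27 and 1 when adjusted over the list alone, and a median of 0.43 in the authors' deposited table (list adjusted p = 8.96e-40). PCK2, mitochondrial phosphoenolpyruvate carboxykinase, stood at 1.68 (SE 0.16), DDIT3 at 1.86 (SE 0.20) and TRIB3 at 1.70 (SE 0.19) in the authors' deposited table. NF-kB targets and cytokines had 7 of 24 called higher, 9 when adjusted over the list alone, and none lower (list adjusted p = 4.76e-08), with IL6 at 1.14 (SE 0.18) and CXCL3 at 1.24 (SE 0.23) in the authors' deposited table. Small nucleolar host genes had 4 of 13 called higher (list adjusted p = 2.1e-05), and immediate early genes 4 of 28 (list adjusted p = 1.42e-05). Mesenchymal genes had 3 of 26 higher (list adjusted p = 0.00677) and epithelial junction and keratin genes 3 of 23 (list adjusted p = 0.0157), calls that ended at a preset correlation of 0.05 (adjusted p = 0.0745 and 0.104). Called lower were 10 of 42 DNA replication genes, 17 when adjusted over the list alone (list adjusted p = 7.07e-12), and 6 of 38 mitosis genes, 10 over the list alone (list adjusted p = 3.79e-07). Cholesterol synthesis genes had 5 of 24 called lower, 11 over the list alone (list adjusted p = 3.92e-11), with MVK, mevalonate kinase, at -1.23 (SE 0.18) in the authors' deposited table. Heat shock chaperones had a median of -0.22 over 15 members in the authors' deposited table and no member called (list adjusted p = 0.00109).

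EIF5A, the substrate of hypusination (chromosome 17, 7306999 to 7312463, GRCh38), had a log2 fold change of -0.39 in cytoplasm (SE 0.16, adjusted p = 0.0486) and -0.44 in polysomes (SE 0.14, adjusted p = 0.0041) in the authors' deposited table. Its whole-cell value in the authors' deposited table, with the sign reversed, was 0.45, with an unadjusted p of 0.524. DHPS, at -0.14 (SE 0.23) in cytoplasm and 0.00 in polysomes, and DOHH, at -0.54 (SE 0.35) and -0.27 (SE 0.17), were not called in the authors' deposited table. Their deposited values are shrunken, and the unshrunken cytoplasmic values were -0.56 (SE 0.38) for DHPS and -0.79 (SE 0.30) for DOHH. The polyamine genes ODC1, SAT1 and AMD1 were likewise not called, with values of 0.17, -0.04 and -0.02 in cytoplasm and 0.14, -0.28 and -0.25 in polysomes in the authors' deposited table. The unshrunken cytoplasmic value of ODC1 was 1.03 (SE 0.53), so a change of that size is not excluded. OAZ2, an inhibitor of ornithine decarboxylase, was lower in polysomes at -0.53 (SE 0.14, adjusted p = 0.000613) and stood at -0.39 (SE 0.16, adjusted p = 0.0585) in cytoplasm in the authors' deposited table. Of the 21 genes of eIF5A and polyamine metabolism, 1 was called higher and 1 lower in cytoplasm, and 1 higher and 3 lower in polysomes. Enzymes that cut mitochondrial tRNAs out of their precursors had no call either: the authors' deposited table gives cytoplasmic values of -0.33 for HSD17B10, -0.11 for TRMT10C, 0.03 for PRORP and 0.14 for ELAC2, and -0.02 for the CCA-adding enzyme TRNT1. As a list, the 36 genes of mitochondrial tRNA processing did not pass the test (list adjusted p = 0.129 in whole cells, 0.973 in cytoplasm and 0.362 in polysomes). Their whole-cell median was -0.16 in the authors' deposited table, with 28 of 36 negative, and other members were called, 1 higher and 1 lower in cytoplasm and 2 higher and 1 lower in polysomes.

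In polysomal RNA, which asked which mRNAs changed on heavy polysomes, more genes passed than in cytoplasm. The authors' deposited table held 1746 genes with an adjusted p under 0.05, 883 higher and 863 lower, and 214 with a fold change over 1 in size as well. Such counts depend on the SE, which differed between fractions in either direction. The unshrunken SE was 0.53 in cytoplasm and 0.16 in polysomes for ODC1, and 0.15 and 0.24 for ASNS. More calls in polysomes are therefore no measure of a larger effect there. GDF15 was again highest among named genes at 4.06 (SE 0.30), followed in the authors' deposited table by IL24 at 2.90 (SE 0.27), IL1RL1 at 2.67 (SE 0.25), CLGN at 2.55 (SE 0.22), LCN2 at 2.28 (SE 0.17) and MMP1 at 2.19 (SE 0.43). MT-CYB was lowest at -4.80 (SE 0.51), with MT-CO3 at -4.69 (SE 0.48) and MT-ND3 at -4.68 (SE 0.57) in the authors' deposited table. The 13 mitochondrially encoded mRNAs had a median of -4.20 and 12 calls in the authors' deposited table, 12 also when adjusted over the list alone (list adjusted p = 7.44e-47). MT-ND6, at -0.09 (SE 0.20), and MT-RNR1, at -0.02 (SE 0.19), were not called in the authors' deposited table, and MT-RNR2 stood at -1.08 (SE 0.57, adjusted p = 0.0251).

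ATF4 targets had 29 of 43 called higher in polysomes and 2 lower, 35 and 2 when adjusted over the list alone (list adjusted p = 7.44e-47), with a median of 0.76 in the authors' deposited table. Small nucleolar host genes had 8 of 13 higher (list adjusted p = 7.13e-08), led by GAS5 at 1.69 (SE 0.22) in the authors' deposited table. Epithelial junction and keratin genes had 8 of 23 higher (list adjusted p = 1.05e-05), among them KRT7 at 1.00 (SE 0.23) and CLDN7 at 0.69 (SE 0.14) in the authors' deposited table. Mesenchymal genes had 7 of 26 higher and 1 lower (list adjusted p = 0.00142), NF-kB targets 5 of 24 higher (list adjusted p = 0.00011), and collagens with their processing enzymes 3 of 22 (list adjusted p = 0.000936). The latter included SERPINH1, a collagen chaperone, at 0.91 (SE 0.19) in the authors' deposited table. TCA cycle genes had 6 of 22 higher (list adjusted p = 0.00164), with IDH1 at 0.86 (SE 0.20) in the authors' deposited table. Mitochondrial chaperones and proteases had 5 of 15 higher and 1 lower (list adjusted p = 0.0123), with HSPA9, the mitochondrial HSP70, at 1.29 (SE 0.24) in the authors' deposited table, and lost the call at a preset correlation of 0.05 (adjusted p = 0.055). Ribosome biogenesis genes had a median of 0.16 with 1 of 28 called (list adjusted p = 0.000936) in the authors' deposited table. Translation factors had 7 of 43 higher and 1 lower (list adjusted p = 0.00245), immediate early genes 6 of 28 higher (list adjusted p = 0.00432), mitochondrial aminoacyl-tRNA synthetases 2 of 20 higher and 1 lower (list adjusted p = 0.0387), and genes of the unfolded protein response 7 of 22 higher and 3 lower (list adjusted p = 0.0471). Those 4 calls ended at a preset correlation of 0.05, with adjusted p-values of 0.0563, 0.0548, 0.123 and 0.151.

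Lower in polysomes were 16 of 42 DNA replication genes (list adjusted p = 5e-10), 10 of 38 mitosis genes (list adjusted p = 9.19e-08) and 8 of 24 cholesterol synthesis genes (list adjusted p = 7.13e-08). TYMS, thymidylate synthase, stood at -0.83 (SE 0.12), BIRC5 at -0.76 (SE 0.14) and INSIG1 at -1.18 (SE 0.15) in the authors' deposited table. Subunits of the respiratory chain encoded in the nucleus were lower, with 7 of 37 complex I genes called lower and 1 higher (list adjusted p = 0.00116) and 9 of 40 genes of complexes II to V lower and 1 higher (list adjusted p = 0.000193). NDUFB3 at -0.65 (SE 0.19) and ATP5MC3 at -0.70 (SE 0.15) are examples from the authors' deposited table. Their unshrunken cytoplasmic values were -0.17 (SE 0.19) and 0.06 (SE 0.37), while other members were lower there too, such as NDUFB4 at -0.74 (SE 0.3). These genes have short coding sequences, with medians of 435 and 398 bases, and short genes were lower in general, with an unshrunken polysomal median of -0.151 over the 2583 shortest. The unshrunken medians of both lists were -0.26 and -0.24, where lists matched on coding length had -0.14 for each. In cytoplasm 31 of 37 and 27 of 40 members were negative in the authors' deposited table, and neither list passed there (list adjusted p = 0.072 and 0.152). In translational efficiency neither list passed (list adjusted p = 0.9 and 0.396), with medians of 0.17 and 0.06. Mitochondrial ribosomal proteins had 11 of 82 lower and 2 higher (list adjusted p = 0.00216), which ended at a preset correlation of 0.05 (adjusted p = 0.0875). Replication-dependent histones had 4 of 19 lower (list adjusted p = 2.02e-05), with H1-5 at -1.28 (SE 0.39) in the authors' deposited table. Metallothioneins had 3 of 9 lower (list adjusted p = 0.0278) and heat shock chaperones 2 of 15 lower (list adjusted p = 0.0417), 2 calls that ended at a preset correlation of 0.05 (adjusted p = 0.0636 and 0.116). In whole cells the medians of histones and metallothioneins had the opposite sign in the authors' deposited table, at 0.33 with 13 of 19 positive and 0.39 with 8 of 9 positive. Neither list passed there (list adjusted p = 0.324 and 0.0848), though metallothioneins did with ranks (adjusted p = 0.0434). The difference between whole cells and polysomes was not tested.

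**Figure D2:**
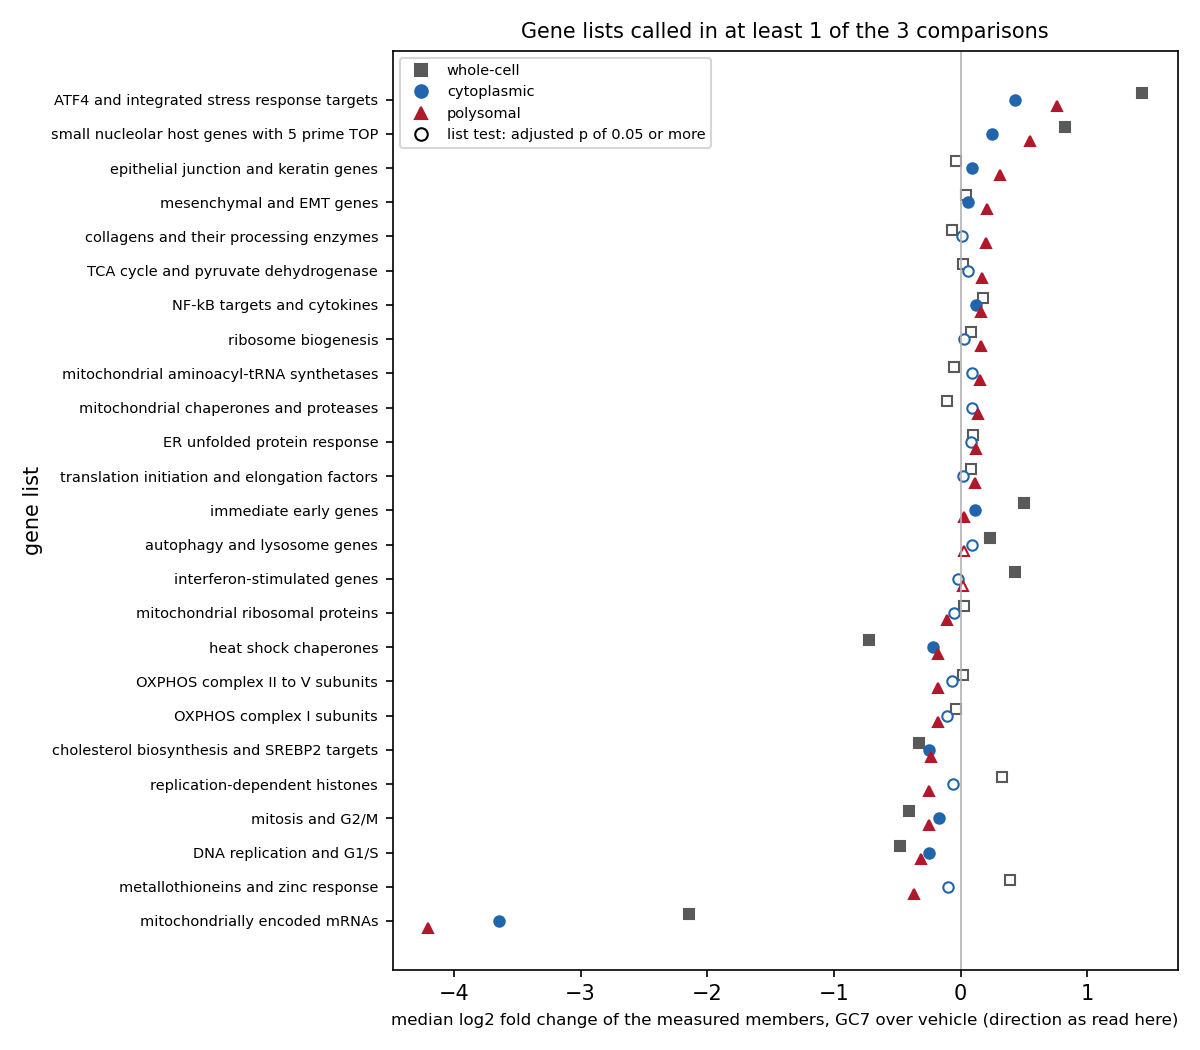
Median log2 fold change of the measured members, on the horizontal axis, of each gene list on the vertical axis that was called in at least 1 comparison, taken from the authors' deposited table. Filled symbols mark lists with a list adjusted p under 0.05, and mitochondrially encoded mRNAs lie at medians of -2.14, -3.64 and -4.20 in whole cells, cytoplasm and polysomes. Medians of cytoplasm and polysomes are of shrunken values, so their sizes are not compared with those of whole cells.

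Not called in whole-cell, cytoplasmic or polysomal RNA were the lists of eIF5A and polyamine metabolism, mitochondrial DNA maintenance, cytosolic ribosomal proteins, p53 targets, fatty acid synthesis, glycolysis, hypoxia targets, proline-rich actin regulators, prostate luminal genes, NRF2 targets and nuclear-retained RNAs. Their polysomal list adjusted p-values were 0.141, 0.69, 0.141, 0.23, 0.675, 0.69, 0.496, 0.938, 0.612, 0.374 and 0.768. Other settings of the test gave calls for 2 of these lists. Cytosolic ribosomal proteins, with a whole-cell median of 0.24 and 62 of 77 positive in the authors' deposited table, went from a list adjusted p of 0.0631 to 0.00146 with ranks and 0.0211 with fold changes, and in polysomes from 0.141 to 0.0421 with ranks. For p53 targets, at a whole-cell median of 0.33 in the authors' deposited table, it went from 0.0511 to 0.0449 with fold changes. Neuroendocrine, fibroblast, endothelial and immune marker lists had 2, 4, 1 and 3 measured members, too few for a test.

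Translational efficiency compared the change in polysomes with the change in cytoplasm, after undoing the shrinkage of the deposited fold changes. No gene of 15669 passed Benjamini-Hochberg adjustment of a normal test of the difference, and 335 had an unadjusted p under 0.05 where 783 would be reached by chance. The count of 0 rests on taking the errors of both fractions as independent, which is uncertain because polysomes were separated from the lysates. With assumed error correlations of 0.3, 0.5 and 0.7 it became 1, 20 and 418. The z values were narrower than a standard normal, with a median size of 0.601 against 0.674. This narrow spread and the 335 against 783 point to an SE of the difference that was mostly too large. The count of 0 therefore does not show a lack of change. Among single genes chosen after their values were seen, MT-RNR1 had the smallest p, with a polysomal minus cytoplasmic difference of 2.44 (SE 0.62, unadjusted p = 7.44e-05). Others were CRY1, a clock repressor, at -1.55 (SE 0.45, unadjusted p = 0.000656), GEN1 at 1.06 (SE 0.32, unadjusted p = 0.000896) and MT-ATP8 at -2.24 (SE 0.68, unadjusted p = 0.000996). MT-ATP8 overlaps MT-ATP6 on chromosome M (8366 to 8572 and 8527 to 9207), and MT-ATP6 differed by -0.29 (SE 0.73). How overlapping reads were counted may therefore bear on the MT-ATP8 value. Mitochondria were pelleted before the gradients, and mitochondrial genes took 0.685% of polysomal counts. For mitochondrially encoded RNAs the difference may thus come from mitochondria left in a fraction and is not read as translational efficiency. Of the 112 genes in the authors' categories for polysomes alone, in the authors' deposited table, 8 had an unadjusted p under 0.05 for this difference, and of the 64 in the categories for cytoplasm alone, 14 did. Over all genes it was 335 of 15669. The categories were set from the same fold changes, so a difference is built into them and these shares are no test.

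As a group, collagens and their processing enzymes had a higher fold change in polysomes than in cytoplasm, with a median difference of 0.41 over 22 members and 18 of them positive (list adjusted p = 0.000185, and 0.0167 at a preset correlation of 0.05). Their unshrunken medians were 0.01 in cytoplasm, with 11 of 22 positive (list adjusted p = 0.991), and 0.38 in polysomes, with 16 positive, and members differed, with COL1A1 at -0.87 (SE 0.35) and COL3A1 at -1.67 (SE 0.91) in cytoplasm. COL1A1, COL1A2 and COL3A1 are also fibroblast markers, 4 of which were measured, all 4 with a positive difference and a median of 1.17. Without these 3 collagens the median difference was 0.24 over 19 members, 15 of them positive (list adjusted p = 0.00313), and the call ended at a preset correlation of 0.05 (adjusted p = 0.0719). SERPINH1 differed by 0.73 (SE 0.28), COL6A2 by 0.60 (SE 0.27), COL6A1 by 0.87 (SE 0.39) and COL1A2 by 1.70 (SE 0.84). Ribosome biogenesis genes had a median difference of 0.25 (list adjusted p = 0.00991). Negative medians were found for mitochondrially encoded mRNAs at -0.56 (list adjusted p = 0.026), NF-kB targets at -0.23 (list adjusted p = 0.026), immediate early genes at -0.16 (list adjusted p = 0.018) and replication-dependent histones at -0.36 (list adjusted p = 0.0294). The mitochondrial median is not read as translational efficiency, for the reason given above. Each of these 5 calls ended at a preset correlation of 0.05, with an adjusted p of 0.161. Examples are IL6 at -0.57 (SE 0.22), MYC at -0.94 (SE 0.41), H4C14 at -1.20 (SE 0.56) and BOP1 at 0.58 (SE 0.31). None of these members passed adjustment over all genes. ATF4 targets, with a median of 0.07, did not pass (list adjusted p = 0.148), although PHGDH, the first enzyme of serine synthesis, differed by 0.79 (SE 0.28, unadjusted p = 0.00391).

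Whole-cell and cytoplasmic fold changes were compared across genes, which are not independent replicates. Over 14083 genes Pearson's correlation of the authors' deposited table for whole cells with the unshrunken cytoplasmic values was 0.36 and Spearman's 0.27. The sign of this correlation was set by the reading of the directions and is no result. Cytoplasmic and polysomal values correlated at 0.66 and 0.60 over 15669 genes. Of genes with an adjusted p under 0.05 in the authors' deposited table, 282 were higher and 194 lower in both fractions, where independent lists would share 20.2 and 16.8, and 0 went opposite ways. Among 14114 genes in both tables, 99 of the 294 higher in whole cells at an unadjusted p under 0.05 were also called higher in cytoplasm in the authors' deposited table, where independent lists would share 7, and 25 were lower in both against 3.3. Opposite calls numbered 1 and 0, but the whole-cell sign was reversed to go with the fractions, so the direction of this overlap is no result either. Polysomes were separated from the lysates, and groups share replicate numbers, so variation between cultures could give shared calls without an effect of GC7. The number for independent lists is therefore not the value with no change, and that value could not be had without per-library values. The tables were normalized separately, and no difference between them was tested. Polysomal against cytoplasmic RNA in vehicle-treated cells was not analysed here.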

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

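The tests on mitochondrial RNAs and nuclear copies were chosen after the results were seen, and those on the whole collagen list before their own results, the GC test once a GC trend across all genes had been seen, and those without 3 of its members after. Every direction rests on the reading of the tables given above.

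The change with GC7 differed between polysomes and cytoplasm, by the list test of the difference itself, for 6 lists: collagens (adjusted p = 0.000185), ribosome biogenesis (adjusted p = 0.00991), immediate early genes (adjusted p = 0.018), mitochondrially encoded mRNAs (adjusted p = 0.026), NF-kB targets (adjusted p = 0.026) and replication-dependent histones (adjusted p = 0.0294). At a preset correlation of 0.05 the collagen list alone passed, at 0.0167, but not without 3 members that are also fibroblast markers (adjusted p = 0.0719), and the other 5 stood at 0.161.

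Mitochondrially encoded mRNAs were lower with GC7 in the 3 comparisons. A different carry-over of mitochondria into the lysates would leave whole cells near 0, but the whole-cell median was -2.14 with 13 of 13 lower, which argues against it as the whole cause. Carry-over may still be a part of the cytoplasmic value, which was not tested. For a loss of all mitochondrial RNA alike in the fractions, 3 RNAs were set against the median of the other 12 mRNAs. The unshrunken changes of 2, MT-RNR1 and MT-ND6, differed from it by more than 1 and by more than 2 SE in both fractions. In cytoplasm MT-ND6 lay 3.12 above that median and MT-RNR1 1.25 above, and in polysomes 4.02 and 4.23 above. But in cytoplasm MT-RNR1, at -2.54 (SE 0.39), lay among the other mRNAs, with MT-ATP8 at -2.31 (SE 0.31) and MT-ND4L at -2.4 (SE 0.26). A loss of all alike is thus argued against by MT-ND6 in both fractions and by MT-RNR1 in polysomes only. In whole cells MT-ND6, at -2.69 in the authors' deposited table, lay with the other mRNAs, while MT-RNR1 stood at 2.29 there and at -2.42 in cytoplasm. Whether libraries were made by poly(A) selection or rRNA depletion is not given in the sources used here. This limits what the rRNA values show and may limit those of MT-ND6 too. An effect of GC7 on mitochondrial transcripts stays open as a hypothesis, with strand-specific loss and the authors' counting of overlapping mitochondrial reads untested.

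Nuclear copies of mitochondrial genes fell too. For 5 of 5 copies the unshrunken cytoplasmic change lay within 2 SE of the parent gene, which is consistent with reads shared with the mitochondrial transcripts. The differences ran from -0.28 for MTRNR2L1 to 1.04 for MTATP6P1, with SE of 0.68 and 0.66, so the test separates only large differences.

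The collagen list had a higher change in polysomes than in cytoplasm, with unshrunken medians of 0.38 and 0.01 and 0 of its 22 members called for the difference. Lists matched on coding length had a median of 0.06, and 0 of 10000 reached the observed 0.41. Of 10000 lists matched on GC and length, with a median of 0.14, 5 reached it. Without COL1A1, COL1A2 and COL3A1, which are also fibroblast markers and have differences with SE of 0.52, 0.84 and 1.05, the median was 0.24, which 224 lists matched on length and 1141 matched on GC and length reached. Genes of such lengths thus had a typical difference of 0.06, under the observed medians. The matched lists draw genes singly, without the variation that members of a list may share. Their counts can therefore understate how often such a median arises. They do not decide against length or GC alone, with or without these members. Over all genes the difference follows GC, with a Spearman correlation of 0.254.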

How the results depend on the processing

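The size threshold was planned and every other alternative was chosen after seeing the data. No paired analysis was possible because the tables hold comparisons and no per-library values. For the same reason the other normalizations, tools, filters, left-out replicates, pseudocounts, estimated list correlations, rotation tests and other splits of the samples were not run, so chance groupings of the libraries could not be counted. With 0 whole-cell genes at an adjusted p under 0.05, the count stayed 0 with the size threshold, over genes with reads and over shared genes, and was 1336 at an unadjusted p under 0.05 and 337 under 0.01. The 668 cytoplasmic genes became 166 with the size threshold and 338 at an adjusted p under 0.01. The 1746 polysomal genes became 214 and 932. These are stricter thresholds on the same p-values. Recomputed adjustment, a threshold of 0.1 and leaving out mitochondrial genes kept both counts within 1.5 times. For translational efficiency the count was 0 with the normal test and with the size threshold, 335 at an unadjusted p under 0.05, 1 with deposited folds and SE, and 1, 20 and 418 with assumed error correlations of 0.3, 0.5 and 0.7, which shrink the SE by construction. The correlation of whole-cell and cytoplasmic values lay between 0.35 and 0.40 under its alternatives. The number of lists called moved in polysomes from 23 to 15 at a preset correlation of 0.05 and to 15 with fold changes, and in translational efficiency from 6 to 1 at 0.05, 3 with ranks and 3 with fold changes. The cause was not tested beyond the larger assumed correlation. Over single lists, 17 calls were lost at 0.05, 8 with ranks, 13 with fold changes and 1, autophagy genes at 0.0856, over all whole-cell genes with reads. With ranks 5 calls were gained, cytosolic ribosomal proteins in whole cells (0.00146) and polysomes (0.0421), metallothioneins in whole cells (0.0434), and complex I (0.0077) and autophagy genes (0.0338) in cytoplasm. With fold changes 3 were gained, cytosolic ribosomal proteins (0.0211) and p53 targets (0.0449) in whole cells and complex I in cytoplasm (0.0219). In these settings 0 calls turned direction. The collagen call in translational efficiency held without members of the fibroblast list (0.00313) and ended without them at a preset correlation of 0.05 (0.0719). Depth per library is unknown, which limits what can be said of genes without a call.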

Other observations

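The tests of proline motifs and of coding length were set before their results were seen, those of coding length in single lists once the lists' medians and the trend across genes were known.

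eIF5A is known to help ribosomes through runs of proline, so a hypothesis was that genes encoding the PPP motif would have a higher change in polysomes than in cytoplasm, as the collagen list had. Of the 22 measured members of that list 5 carry PPP, so the motif could bear on only part of it. For 3377 genes outside that list with a PPP motif, the median minus that of genes matched on coding length and GC was -0.017 (95% bootstrap interval -0.035 to 0.001). The prediction was not met. Without matching, the medians were 0.049 with PPP and -0.005 without it, which is the direction of the hypothesis. For the PPG motif, carried by 2761 genes and by 15 of the 22 collagen list members, the matched difference was -0.019 (interval -0.039 to 0.002), again not met. The unmatched medians were 0.062 with PPG and -0.005 without it. Matching on GC and length may also remove part of a motif effect, which was not tested. The intervals treat genes as independent, which they are not.

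Another hypothesis was that the difference follows coding length, since a short mRNA has room for fewer ribosomes. Across 12870 genes the partial Spearman correlation with coding length, given expression and GC, was 0.189. The median difference was -0.078 in the 2583 genes with the shortest coding sequences (median 543 bases) and 0.041 in the 2571 with the longest (median 3516 bases), with 0.061 in the 2577 genes next to the longest. The shortest group had a median of -0.068 in cytoplasm and -0.151 in polysomes. A lower number of ribosomes per mRNA with GC7 and a different set of gradient fractions collected could each give such a trend, and no value here separates them.

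Nuclear-encoded genes of the respiratory chain and of the mitochondrial ribosome were lower in polysomes as lists, and their coding sequences are short. Of 10000 lists matched on coding length, 206 had an unshrunken polysomal median as low as the -0.26 of complex I, 531 as low as the -0.24 of complexes II to V and 976 as low as the -0.17 of mitochondrial ribosomal proteins. The matched medians were -0.14, -0.14 and -0.11. Coding length may therefore account for part of these values. The lower values need not be particular to polysomes. In cytoplasm 31 of 37, 27 of 40 and 51 of 82 members of these lists were negative, though no list passed there. Their median polysomal minus cytoplasmic differences were 0.17, 0.06 and -0.01, where the shortest genes had -0.078. For complex I the observed median lay under the bound of 2.5% set for the test, though 3 lists were tested and the margin is small. The matched lists also lack the variation that members of a list may share. Length as the whole cause therefore stays open for all 3 lists.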
